A study of Mus musculus with 6 samples.

How the data were processed

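RNA was measured in retinas of mouse embryos on a C57BL/6J background at embryonic day 13.5, in 3 wild-type and 3 Tbx3 conditional knockout (Tbx3 cKO) libraries. Per the labels' protocols, Tbx3 was deleted by crossing floxed Tbx3 mice with the Dkk3-Cre line, and the wild types were Cre-negative siblings with 1 floxed and 1 normal Tbx3 allele. Polyadenylated RNA was selected on magnetic beads and made into strand-specific libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. The labels do not say how many embryos or retinas made up a library or which libraries shared a litter, so the p-values measure the spread between these 6 samples, part of which may be technical.

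Per the submitters' processing notes, cutadapt 4.2, STAR 2.7.8a, Partek and the mouse build GRCm39 (mm39) were used. The role of each tool, the counter, the annotation, the use of strand and the method of scaling are not given in the sources used here. The deposited values are a signal, taken here as estimated counts of reads per gene divided by 1 factor per library by the authors. This was read from the values, which are not whole and whose most frequent low values are multiples of a step of 0.897 to 1.138 per library. Of the values up to 20 steps, 76.1 to 78.2% per library lay within 0.02 steps of a whole multiple, and 81.8 to 83.5% within 0.1 steps. The other low values lay between multiples, so whole reads could not be recovered. Reads shared between overlapping genes or near-identical copies and split by estimate would give such values, but whether they did was not tested. Values of close copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b) and of genes with an antisense partner (Vax2 and Vax2os, Tbx3 and Tbx3os1) are taken as uncertain. The column totals were 23504342 to 25006748, which with the steps gives an estimated 21482340 to 27173677 reads per library. A value of 0 allows up to 3 reads, or 2.69 to 3.41 in normalized units, and this floor covers counting error only. The file lists 26147 genes, of which 108 have no symbol and hold 0.041% of the total. Gene symbols and identifiers were taken from the file. No coordinates are given, because the annotation at hand is of another build than the one in the processing notes.

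Genes with a value of at least 10 in at least 3 libraries (18914) were tested, and 7233 were not. Values were taken as log2(value + 1), so fold changes understate the change of low genes. The groups were compared with limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate or replicate block was used. Levels are mean ± SD of the normalized values, and single genes were also compared with exact two-sided permutation tests, which cannot give a p under 0.1 with 3 against 3. A set of 25 gene lists, 405 entries in all with 379 tested, was compared with camera from limma at a preset correlation of 0.01, adjusted over the lists. The same lists were run with a correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance without setting them against other genes. Bambi, Id3, Vax1, Hes1, Hes5, Notch1, Msx1, Ntn1, Cdkn1a, Adm and Vegfa each stand in more than 1 list.

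The lists, the tests, the filter, the rule for naming genes and most alternatives were set before the data were examined. Named were 8 genes always (among them Tbx3, Tbx2, Tbx5, Vegfa, Pdgfa, Atoh7 and Pou4f2) and up to 8 genes per direction past the threshold with the largest fold change, no overlap between groups, a mean of at least 100 in the higher group and a symbol that is not a model name. Of the genes this rule takes, 2 are not reported here by name. From each list the 2 members of smallest p were taken, or 4 where camera called the list. Other genes are named as list members or are said to have been chosen after their values were seen. Alternatives covered the pseudocount, the filter, the normalization (TMM and median-of-ratios factors, quantile normalization and equal totals), the replicate number as a block, the empirical Bayes step, library weights, leaving out each library, the list test and the threshold. Added after seeing the data were fits without wild type 1 and Tbx3 cKO 3, fits with a term for the globin ratio (embryonic Hbb-y over adult Hbb-bs and Hbb-bt), for lens genes or for sex read from Xist, a fit within the 4 libraries of high globin ratio, and limma-voom on the estimated reads.

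The steps were tested on simulated counts for the 18914 genes with the means and library sizes of the real samples. Changed genes were drawn from those with a mean of at least 100, and genes varied independently. Recovery of lower genes, or of genes that vary together, was therefore not tested. The adjusted threshold is easier to pass where many genes change, so the rates may overstate recovery in the real data. With the dispersion of the real libraries, 6, 42, 82 and 92% of 50 genes each changed by 1.5, 2, 4 and 8 times were recovered, and 9 unchanged genes (7.5% of the calls) were called. With a dispersion of 0.02 for every gene, 44, 98, 100 and 100% were recovered.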

Results

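Transcript levels were measured in the retina of mouse embryos at embryonic day 13.5, in 3 wild-type and 3 Tbx3 cKO libraries. Tbx3 encodes a T-box transcription factor of the dorsal retina. The comparison asks what its loss changes in genes of retinal cell formation and of vessel growth, both named in the title of the study. The wild types were Cre-negative, so an effect of Cre itself cannot be told apart from loss of Tbx3. Growth of vessels was not measured. The values do not tell whether endothelial transcripts came from the retina or from tissue around it. The libraries held an estimated 21482340 to 27173677 reads each, and 18342 to 19322 genes per library had a normalized value of at least 10. Of the 26147 genes in the file, 18914 were tested.

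Loss of Tbx3 came with lower dorsal and higher ventral patterning genes. Tbx3 itself (ENSMUSG00000018604) had normalized values of 1998, 2558 and 2577 in wild type and 40.3, 47.8 and 58.9 in Tbx3 cKO. It was 47.8-fold lower in the cKO, with a log2 fold change of -5.58 (SE 0.20) and an adjusted p of 0.000342 by limma-trend. The exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. The same test gave 0.1 for Tbx2 and Tbx5, 0.2 for Atoh7 and Pou4f2, and 0.3 for Vegfa and Pdgfa. The labels do not name the deleted exons, so reads of exons left in place can remain.

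After adjustment over all genes, 12 genes differed between the groups, 6 lower and 6 higher in Tbx3 cKO, and none of them had overlapping values. Lower beside Tbx3 were Tbx5 (ENSMUSG00000018263), a second dorsal T-box factor, which fell from 761 ± 112 to 20.1 ± 11 (SD, n = 3 each), and Tbx2 (ENSMUSG00000000093), which fell from 3127 ± 296 to 864 ± 233. Id1 (ENSMUSG00000042745), a target of BMP signalling, fell from 1636 ± 106 to 422 ± 78.3. Efnb2 (ENSMUSG00000001300), the dorsal ephrin ligand, fell 3.37-fold, and the protocadherin Pcdh17 (ENSMUSG00000035566) fell 3.09-fold. Higher were Smoc1 (ENSMUSG00000021136), a secreted modulator of BMP signalling, from 1236 ± 357 to 13398 ± 4295, and the ventral homeobox factor Vax1 (ENSMUSG00000006270), from 67.8 ± 16.1 to 644 ± 243. Aldh1a3 (ENSMUSG00000015134), which makes retinoic acid in ventral retina, rose from 6726 ± 1701 to 26564 ± 2709. The dehydrogenase Hsd17b11 (ENSMUSG00000029311) rose 4.43-fold. Also higher was the gene model Gm59783 (ENSMUSG00000126572), by 8.76-fold, named here after its values were seen. Adjusted p of the 11 genes beside Tbx3 ran from 0.0180 to 0.0378 by limma. At an unadjusted p under 0.05 stood 2562 genes (1208 higher and 1354 lower), and 22.4% of tested genes had no overlap between groups, where chance gives 10%. Leaving out any 1 library other than Tbx3 cKO 3 left 1 called gene, Tbx3. Without Tbx3 cKO 3, 10 genes were called, 7 of them among the 12, and with wild type 1 and Tbx3 cKO 3 both left out 42 were called, 11 of them among the 12.

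**Figure D1:**
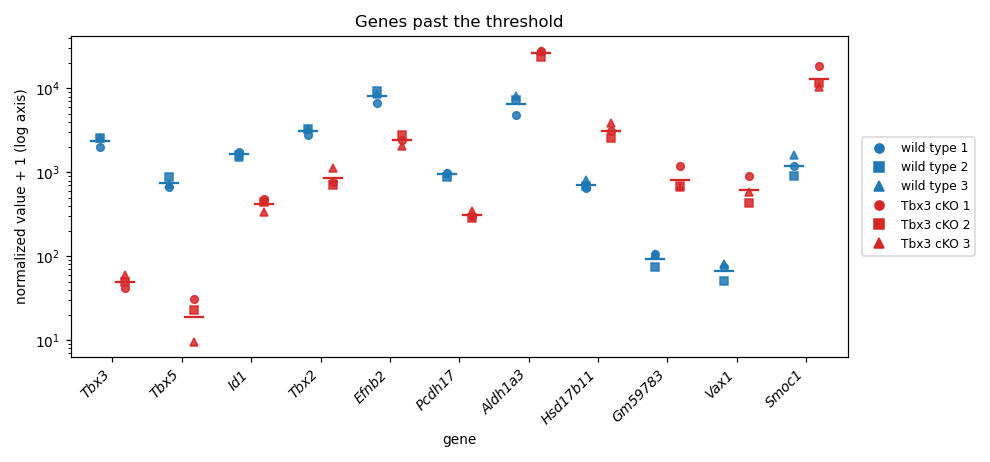
Normalized value + 1 on a log axis in each of the 6 libraries for 11 of the 12 genes past the limma threshold, ordered from the most lowered to the most raised. Points are libraries, short lines are group means on the log scale, and the groups do not overlap for any of the 11 genes, with Tbx3 at 1998 to 2577 in wild type and 40.3 to 58.9 in Tbx3 cKO.

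As groups, dorsal and BMP response genes were lower and ventral genes higher. Of 11 dorsal genes, 3 fell over all genes tested (Tbx5, Efnb2 and Tbx2) and 5 fell adjusted over the list alone, with Gdf6 and Bambi added. The dorsal list had a median log2 fold change of -1.54 (camera adjusted p = 6.04e-06, and adjusted p = 0.294 with an estimated correlation). In it 9 members were negative and 2 positive. Gdf6, a BMP ligand of the dorsal eye, was 413 ± 77.4 in wild type and 6.06 ± 5.96 in Tbx3 cKO (adjusted p = 0.0530 by limma over all genes). Of 11 ventral genes, 3 rose over all genes (Smoc1, Aldh1a3 and Vax1) and 7 rose adjusted over the list alone. The ventral median was 1.11 (camera adjusted p = 4.89e-06, and adjusted p = 0.294 with an estimated correlation), with 8 members positive and 3 negative. Vax2 was 1292 ± 213 against 3875 ± 899. All 11 BMP response genes had a negative log2 fold change, with a median of -0.81 (camera adjusted p = 9.95e-07, and adjusted p = 0.133 with an estimated correlation). Id1 fell over all genes, and 6 members fell adjusted over the list alone, among them Id2 with 2233 ± 216 against 612 ± 229 and Smad9 with 130 ± 30.3 against 12.7 ± 14.5. With wild type 1 and Tbx3 cKO 3 left out, the medians were -1.78 for dorsal, 0.94 for ventral and -1.40 for BMP response genes. By fry, the adjusted p was 0.0266 for the dorsal, 0.0225 for the ventral and 0.00769 for the BMP response list. The optic stalk and astrocyte list had a median of 0.54 (camera adjusted p = 0.0339, and adjusted p = 0.435 with an estimated correlation). Vax1 was its only member to pass, over all genes and adjusted over the list alone, and Pax2 was 363 ± 66.2 against 1305 ± 1121. The optic stalk call was lost without wild type 3, Tbx3 cKO 1 or Tbx3 cKO 3 (adjusted p 0.0815, 0.0942 and 0.0571). It was also lost with equal totals (0.0565), with a term for lens genes (0.183), within the 4 libraries of high globin ratio (0.119) and with wild type 1 and Tbx3 cKO 3 left out (0.117).

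Genes of retinal ganglion cells, the first neurons to form in the retina, were lower as a list. All 22 tested had a negative log2 fold change, with a median of -2.93 (camera adjusted p = 1.64e-08, and adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone, 12 fell. Over all genes tested no member passed limma, against 14 lower at an unadjusted p under 0.05 and 0 by limma-voom. Examples are the transcription factor Pou4f1, 691 ± 587 in wild type and 66.1 ± 44.2 in Tbx3 cKO, and the neurofilament gene Nefm, 11462 ± 9292 and 1100 ± 944. Pou4f2, a regulator of ganglion cell fate, had values of 4488, 1689 and 2729 in wild type and 1984, 763 and 0 in Tbx3 cKO (log2 fold change -4.58, limma adjusted p = 0.447). A value of 0 in Tbx3 cKO 3 allows up to 3.16 at its depth. Tbx3 cKO 3 was lowest of all libraries in 17 of the 22 genes, and wild type 1 had the highest list score. The median was -2.10 without Tbx3 cKO 3 and -1.25 with wild type 1 also left out (camera adjusted p = 1.71e-08 and 9.46e-10). In 16 of the 22 genes both Tbx3 cKO 1 and 2 lay below every wild-type library, where chance gives 10% each way for a single gene. The genes of the list vary together (estimated correlation 0.637), so they do not count as 22 separate results.

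Genes of neurogenic progenitors, the cells about to leave the cycle, had a median of -1.35 over 20 genes (camera adjusted p = 0.000265, and adjusted p = 0.510 with an estimated correlation). None fell over all genes or adjusted over the list alone by limma, 4 were lower at an unadjusted p under 0.05, and 0 passed limma-voom. Atoh7, the factor that makes progenitors competent for ganglion cell fate, was 17556, 11596 and 14438 in wild type and 11873, 6024 and 4.21 in Tbx3 cKO (log2 fold change -4.32, SE 2.69, limma adjusted p = 0.475). The same library was lowest in 18 of the 20 genes. Without it the median was -0.40 (camera adjusted p = 0.0154), and without wild type 1 as well it was -0.17 (camera adjusted p = 0.121). Amacrine and horizontal cell genes had a median of -2.27 over 15 genes (camera adjusted p = 0.000265, and adjusted p = 0.435 with an estimated correlation), and -0.95 without Tbx3 cKO 3. No member passed limma over all genes or adjusted over the list alone, 3 were lower at an unadjusted p under 0.05, and 0 passed limma-voom. Among them, Tfap2c was 59.7 ± 32.7 against 11.2 ± 13.3. Photoreceptor precursor genes had a median of -0.78 and were not called (camera adjusted p = 0.0531, and adjusted p = 0.510 with an estimated correlation). Crx and Prdm1 fell adjusted over the list alone, from 718 ± 787 to 55.5 ± 48.8 and from 1041 ± 973 to 119 ± 88.3. The photoreceptor list was called without wild type 2, wild type 3 or Tbx3 cKO 3 (adjusted p 0.00701, 0.0222 and 0.00421), but its median was 0.03 without wild type 1 (adjusted p = 0.460) and -0.39 without Tbx3 cKO 2 (adjusted p = 0.227). With all libraries kept it was called in some other fits, such as those with no filter (0.0384), equal totals (0.0313) and a term for lens genes (0.00333).

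**Figure D2:**
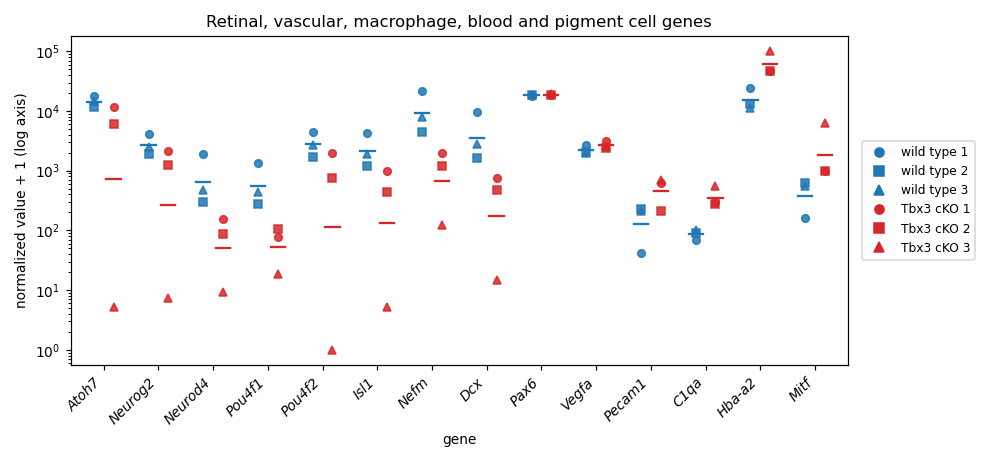
Normalized value + 1 on a log axis in each library for genes of neurogenic progenitors, ganglion cells, retinal progenitors, vessels, macrophages, red blood cells and pigment cells. Points are libraries, short lines are group means on the log scale, and Tbx3 cKO 3 has Atoh7 at 4.21 and Pou4f2 at 0 while Pax6 lies between 17968 and 18941 in all 6 libraries.

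Genes of multipotent retinal progenitors were not called as a list (median -0.69 over 20 genes, camera adjusted p = 0.10, and adjusted p = 0.557 with an estimated correlation). Adjusted over the list alone Lhx2 rose, from 4588 ± 293 to 8446 ± 1139, and Id3 fell, from 4059 ± 530 to 2357 ± 647. Pax6 differed by a log2 fold change of 0.01. The list was called without Tbx3 cKO 1 (median -0.80, adjusted p = 0.0310), while its median was -0.14 without Tbx3 cKO 3 (adjusted p = 0.300). S phase and mitosis genes were lower by small amounts, with medians of -0.24 and -0.19 over 20 genes each (camera adjusted p = 0.000599 and 0.000942, and adjusted p = 0.510 for both with an estimated correlation). No member of either passed limma over all genes or adjusted over the list alone, 0 and 4 were lower at an unadjusted p under 0.05, and 0 passed limma-voom. Mki67 was 29138 ± 1469 against 21726 ± 3122, and Mcm3 was 5880 ± 418 against 4787 ± 771. Without Tbx3 cKO 3 the medians were -0.12 and -0.06, and the mitosis call was lost (adjusted p = 0.0475 for S phase and 0.0603 for mitosis). Without Tbx3 cKO 2 they were -0.38 and -0.32. Notch pathway genes were not called (median -0.42, camera adjusted p = 0.241), with Hey1 at 916 ± 196 against 423 ± 185, and were called without Tbx3 cKO 1 (median -0.70, adjusted p = 0.0336) or within the 4 libraries of high globin ratio (median -0.38, adjusted p = 0.0252). Their median was -0.18 without Tbx3 cKO 3 (adjusted p = 0.411) and 0.01 with wild type 1 also left out (adjusted p = 0.530). Wnt response genes (median 0.14, adjusted p = 0.906), cell cycle inhibitors (median -0.004 and mean 0.20, adjusted p = 0.968) and p53 response genes (median -0.01 and mean 0.28, adjusted p = 0.210) were not called by camera. The p53 list was called without wild type 1 (median 0.25, adjusted p = 0.0270), and its median was -0.06 without wild type 3 (adjusted p = 0.565).

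The secreted factors that promote or restrain vessel growth were higher as a list, with a median of 0.52 over 23 genes (camera adjusted p = 0.00241, and adjusted p = 0.463 with an estimated correlation). Adjusted over the list alone 1 gene rose, Wnt7b, a ligand that acts on vessels of the nervous system, from 322 ± 129 to 2006 ± 584 (limma adjusted p = 0.0658 over all genes). Vegfa, the main growth factor for endothelial cells, was 2260 ± 417 against 2719 ± 353 (log2 fold change 0.27, 95% interval -0.10 to 0.65, limma adjusted p = 0.450). Pdgfa, which draws astrocytes into the retina, was 147 ± 97.9 against 273 ± 195 (log2 fold change 0.85, limma adjusted p = 0.509). The factor list had a median of 0.30 without Tbx3 cKO 3 (adjusted p = 0.0348), 0.28 without wild type 3 (adjusted p = 0.0116), and 0.18 with wild type 1 and Tbx3 cKO 3 left out (adjusted p = 0.196). Endothelial cell genes had a median of 1.37, with 19 of 20 positive (camera adjusted p = 2.05e-05, and adjusted p = 0.468 with an estimated correlation). None rose over all genes or adjusted over the list alone by limma, 7 were higher at an unadjusted p under 0.05, and 0 passed limma-voom. Pecam1 was 40.1, 226 and 213 in wild type and 617, 212 and 696 in Tbx3 cKO. Wild type 1 was the lowest library of the endothelial score, and the median was 0.65 without it (adjusted p = 0.000448) and 0.41 with Tbx3 cKO 3 also left out (adjusted p = 0.0253). Hypoxia response genes were not called (median 0.07 and mean -0.004, camera adjusted p = 0.144), but 3 members rose adjusted over the list alone. Egln3 rose from 142 ± 18.1 to 317 ± 37.5, Pdk1 from 1801 ± 183 to 2621 ± 9.56, and Aldoa from 7060 ± 392 to 9209 ± 469. The hypoxia list was called as higher without Tbx3 cKO 3 or wild type 1 (medians 0.30 and 0.16, adjusted p 0.00272 and 0.0274), with both left out (median 0.32, adjusted p = 0.000162) and with library weights (adjusted p = 0.00836). Its median was -0.06 without Tbx3 cKO 1 (adjusted p = 0.620).

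Among lists of other cell types in or around the eye, camera called endothelium (above), red blood cells, macrophages, pigment epithelium and mesenchyme as higher. It did not call the lens. The ciliary margin list, set among those of the retina and its pathways, was also called as higher. Red blood cell genes had a median of 2.24 over 13 genes (camera adjusted p = 1.64e-08, and adjusted p = 0.294 with an estimated correlation), and 11 rose adjusted over the list alone. Their share of the total was 0.390, 0.355 and 0.264% in wild type and 0.834, 1.16 and 2.66% in Tbx3 cKO. Genes of microglia and macrophages had a median of 1.69 over 15 genes (camera adjusted p = 1.67e-10, and adjusted p = 0.368 with an estimated correlation), and 11 rose adjusted over the list alone. The complement gene C1qa rose from 86.6 ± 17.8 to 373 ± 157 and the receptor gene Csf1r from 373 ± 64.6 to 1053 ± 385. Over all genes no member of these 2 lists passed limma, against 11 and 12 higher at an unadjusted p under 0.05 and 0 by limma-voom. With wild type 1 and Tbx3 cKO 3 left out, the medians were 1.77 for red blood cell and 1.02 for macrophage genes. Pigment epithelium genes had a median of 1.70 over 15 genes (camera adjusted p = 3.35e-05, and adjusted p = 0.443 with an estimated correlation), with Mitf at 162, 631 and 546 in wild type and 1001, 986 and 6305 in Tbx3 cKO. No pigment gene passed limma over all genes or adjusted over the list alone, 6 were higher at an unadjusted p under 0.05, and 0 passed limma-voom. The pigment median was 1.12 without Tbx3 cKO 3 and 0.81 without wild type 1 (adjusted p = 0.000456 and 0.000448). Ciliary margin genes had a median of 0.79 over 12 genes (camera adjusted p = 0.000265, and adjusted p = 0.463 with an estimated correlation). Adjusted over the list alone 4 rose, among them Bmp7 from 582 ± 219 to 2770 ± 1409 and the Wnt receptor gene Fzd1 from 1143 ± 485 to 4407 ± 2034. The ciliary call was lost within the 4 libraries of high globin ratio (adjusted p = 0.0617), and the median was 0.30 with wild type 1 and Tbx3 cKO 3 left out (adjusted p = 0.0232). It was 0.25 where Tbx3 cKO 2 was set against wild type 2 and 3, and 2.02 where Tbx3 cKO 1 was set against wild type 1. Mural cell and periocular mesenchyme genes had a median of 1.31 (camera adjusted p = 0.00312, and adjusted p = 0.510 with an estimated correlation). That call was lost without wild type 1 (median 0.54, adjusted p = 0.101) or Tbx3 cKO 3 (median 0.83, adjusted p = 0.0663), and the median was 2.08 without wild type 2 and 0.02 with wild type 1 and Tbx3 cKO 3 both left out (adjusted p = 0.834). Immediate early and heat shock genes, which respond to handling of tissue, had a median of 0.73 (camera adjusted p = 0.0110, adjusted p = 0.294 with an estimated correlation and 0.0225 by fry). Egr1 was 40.0 ± 25.2 against 246 ± 228. Lens genes were not called (median -1.88, camera adjusted p = 0.0959), and were called as lower without wild type 1 or Tbx3 cKO 2 (adjusted p 9.4e-06 and 0.000587). The lens median was -0.57 without wild type 2 (adjusted p = 0.702) and -0.75 without Tbx3 cKO 1 (adjusted p = 0.719), and the list was called as lower in other fits as well, such as those with no filter (0.0371), equal totals (0.0441), the replicate block (0.000923) and library weights (0.000362).

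**Figure D3:**
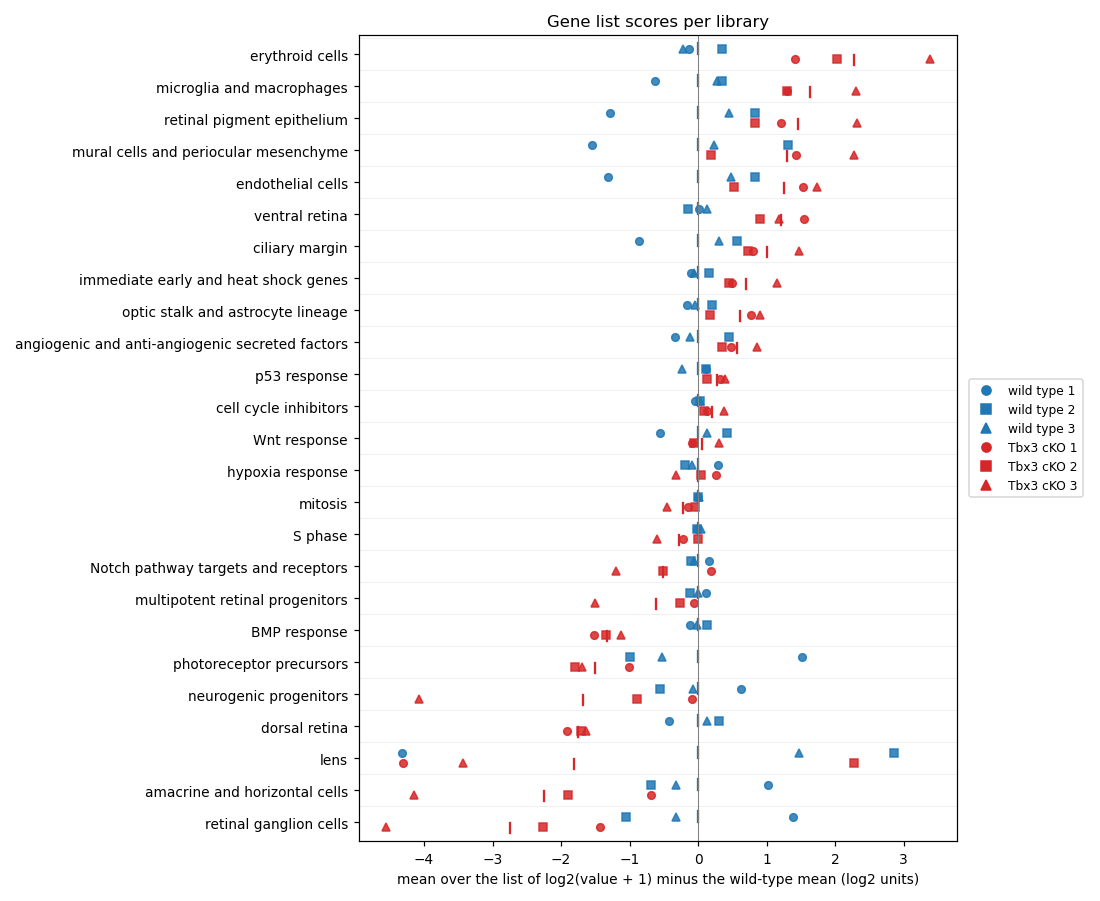
Mean over each of the 25 gene lists of log2(value + 1) minus the wild-type mean, in log2 units, for each library, with lists ordered by the Tbx3 cKO mean. Points are libraries and short lines are group means, and Tbx3 cKO 3 lies at -4.07 for neurogenic progenitors against -0.09 and -0.89 in Tbx3 cKO 1 and 2.

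The libraries also differed within groups. The first principal component held 49.9% of the variance and set wild type 1 (-96.8) and Tbx3 cKO 3 (120) at its ends. Wild type 2 and 3 lay on it at -15.8 and -35.4, and Tbx3 cKO 1 and 2 at 8.03 and 19.5. It therefore also set the 2 groups apart. Lens genes made up 0.856, 0.316 and 0.603% of the total in wild type 2, wild type 3 and Tbx3 cKO 2, and at most 0.00592% in the other libraries. The ratio of embryonic Hbb-y to adult beta-globin was 0.331 in wild type 1 and 0.749 in Tbx3 cKO 1, against 4.78 to 5.81 in the other 4. Xist was at 63016 to 69731 in wild type 2, wild type 3 and Tbx3 cKO 3 and at 122 to 168 in the other 3. Lists were also compared within the libraries that share each of these marks, which left 1 library on a side in 5 of the 6 subsets. Within the 4 libraries of high globin ratio limma called 1 gene, and with a term for the globin ratio or for lens genes it called 100 and 2 genes. The dorsal median lay between -1.89 and -0.48 in these subsets and the ventral median between 0.72 and 1.58. The ganglion cell median lay between -4.73 and -1.71, the red blood cell median between 1.42 and 3.30, and the macrophage median between 1.23 and 2.54. Endothelial and mesenchymal genes were at -0.29 and -0.52 where Tbx3 cKO 2 was set against wild type 2 and 3, and at up to 3.16 and 3.36 in the other subsets.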

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

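The log2 fold change of Tbx3 stayed between -5.84 and -5.39 in the fits run, with its call kept. Pseudocounts of 0.1 and 8, both other filters, the scalings and the robust fit called 11 to 17 genes. Without the mean-variance trend 2 genes were called (0 higher, 2 lower), with library weights 55 (27 and 28), and at an adjusted p under 0.1, 29 (13 and 16). Leaving out 1 library gave 1 to 10 genes (0 to 3 higher, 1 to 7 lower) and 16 to 19 lists, and the adjusted p of the multipotent progenitor list ran from 0.031 to 0.300. Whether the replicate numbers pair the libraries could not be decided. Deviations from the group means correlated at 0.330, 0.0180 and 0.0424 for equal numbers, and at -0.299 to 0.228 for unequal numbers. The highest value was that of wild type 1 with Tbx3 cKO 1. The fit with the replicate block called 13 genes (6 and 7), 10 of them among the 12, and 19 lists. The fits named next were chosen after seeing the data. With wild type 1 and Tbx3 cKO 3 left out 42 genes were called (23 and 19), and the neurogenic progenitor and angiogenic factor lists were not called (adjusted p 0.121 and 0.196). A globin term gave 100 genes (35 and 65), the 4 libraries of high globin ratio 1 (0 and 1), a sex term 1623 (806 and 817) with the multipotent progenitor list called (0.0151), a lens term 2 (0 and 2), and limma-voom 7 (2 and 5). With an estimated correlation camera called 0 lists, with adjusted p of 0.510 for neurogenic progenitors, 0.435 for ganglion cells, 0.463 for angiogenic factors and 0.468 for endothelial cells. By fry 4 lists were called, and the same adjusted p values were 0.389, 0.203, 0.235 and 0.288. Directions turned in lists that were not called. For cell cycle inhibitors the adjusted p was then 0.956 with no filter, 0.851 with a mean of at least 50, 1.0 with equal totals, 0.949, 0.762 and 0.668 with a globin, sex and lens term, 0.950 by fry, and 0.551 to 0.918 without 1 library, turned in 3 of the 6. For Wnt response it was 0.674 with library weights, 0.121 with both libraries left out, 0.514 within the high globin ratio libraries, and 0.469 to 0.960 without 1 library, turned in 3 of the 6. Hypoxia response turned with the sex term (0.912) and lens with the lens term (0.430). The cause of these differences was not tested. The 2 planned count tests were not run, because too few low values were whole multiples of a read. Within 0.1 steps, the tolerance of the rule, 81.8 to 83.5% were, and within 0.02 steps 76.1 to 78.2%. In simulated counts with the dispersion of these libraries 42% of genes changed 2 times were recovered, all with a mean of at least 100. Many changes of that size are therefore not detectable here, and the rate for lower genes was not tested.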

Other observations

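Of 6 genes of retinoic acid metabolism beside Aldh1a3, chosen after their values were seen, none passed limma over all genes. Cyp26a1, which breaks down retinoic acid in a band across the retina, was 920 ± 204 in wild type and 95.8 ± 56.2 in Tbx3 cKO (log2 fold change -3.37, limma adjusted p = 0.0658), and Cyp26c1 was 33.4 ± 12.2 against 4.40 ± 5.89. Aldh1a1, the dorsal enzyme of retinoic acid synthesis, was 11150, 53332 and 42708 in wild type and 9928, 15522 and 6737 in Tbx3 cKO (log2 fold change -1.54, limma adjusted p = 0.355). Stra6, the vitamin A transporter, was 1689 ± 784 against 5323 ± 1557, Dhrs3 was 108 ± 91.2 against 383 ± 295, and Crabp1 was 3340 ± 744 against 820 ± 557. The limma adjusted p of these 6 genes ran from 0.0658 to 0.360. Vax2os, a noncoding RNA antisense to Vax2, was 1643 ± 310 against 9145 ± 3475 (limma adjusted p = 0.0646), and the use of strand in counting is not given.

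The tests in this and the next paragraph and the fit with a sex term were chosen after the results had been seen. The comparison of that fit with other terms and the test on other splits were set before their results were seen. The lower ganglion cell genes do not rest on Tbx3 cKO 3, since their median was still -2.10 without that library. The ratio of embryonic to adult globin falls as embryos age. An age difference between the libraries of high and low ratio does not alone account for the lower ganglion cell genes. Within the 4 of high ratio, 2 per group, the median was -2.51 (camera adjusted p = 2.3e-09 at the preset correlation). List scores there were -1.05 and -0.33 in wild type against -2.26 and -4.56 in Tbx3 cKO. The globin ratios of these libraries were 5.44 and 4.78 against 5.13 and 5.81. Within each group the ganglion cell score fell as the ratio rose, so smaller differences in age are not excluded. The low ratio set holds 1 library per group, with unequal ratios of 0.331 and 0.749, and decides nothing. Dilution of retinal cells by cells that express neither list would lower progenitor and ganglion cell genes alike. The ganglion cell score minus the progenitor score was -1.37, -2.0 and -3.05 in the Tbx3 cKO libraries, against 1.27, -0.94 and -0.33 in wild type. Every Tbx3 cKO value lay below every wild-type value, but the groups lay apart by less than the spread within wild type. Dilution is therefore not excluded, and dilution by cells that express progenitor genes was not tested. The lower neurogenic progenitor genes, unlike those of ganglion cells, may rest on Tbx3 cKO 3, with a median of -0.40 without that library. Fewer or later ganglion cells after loss of Tbx3 is a hypothesis that stays open, as does the age of single embryos, which no label gives.

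The higher red blood cell and macrophage genes do not rest on Tbx3 cKO 3, since the lower of the 2 medians without it was 1.30. The higher endothelial, mesenchymal and pigment genes may rest largely on wild type 1 and Tbx3 cKO 3, because with both left out the highest of the 3 medians was 0.48. More surrounding tissue of every type kept at dissection would raise blood, macrophage and mesenchymal genes alike. Against it, with both libraries left out the medians were 1.77 for red blood cells and 1.02 for macrophages and 0.02 for mesenchyme. Such tissue and a true gain of blood and macrophages still cannot be told apart with so few libraries. The red blood cell score minus the mesenchymal score was 1.42, -0.97 and -0.45 in wild type and -0.01, 1.84 and 1.10 in Tbx3 cKO (exact permutation p = 0.3), so that without wild type 1 the groups lay apart by less than the spread within Tbx3 cKO. The macrophage score minus the mesenchymal score was 0.92, -0.96 and 0.04 against -0.14, 1.12 and 0.02, which overlapped without wild type 1 as well. The most abundant of these genes were Hba-a1, at 16596 ± 4905 against 70056 ± 40585, and Hbb-y, at 26286 ± 13262 against 136800 ± 104405.

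With sex, read from Xist, as a term in the fit, limma called 1623 genes against 12. Of the 18 ways to set 1 wild-type and 1 Tbx3 cKO library apart with such a term, 1 gave that many genes, the sex term itself, and the highest of the others gave 100. The sex term cannot be told apart from the structure of the samples, because it sets wild type 1 against wild type 2 and 3 and Tbx3 cKO 3 against Tbx3 cKO 1 and 2, the same libraries that lie at the ends of the first principal component. The gain may therefore come from the 2 libraries that stand apart.

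Of the 10 splits of the 6 libraries into 3 and 3, 2 gave at least 12 genes, the real one included, and the highest other gave 20. That split set wild type 1, Tbx3 cKO 1 and Tbx3 cKO 3 against the others, the division made by lens genes, and 9 of its 20 genes were in the lens list. With a term for lens genes the real comparison called 2 genes. For the gene lists, the real split called 17 of 25, and the others called 9, 12, 4, 14, 14, 3, 12, 6 and 12. At the preset correlation camera thus called many lists under groupings that mix the genotypes. A camera call alone therefore does not tie a list to loss of Tbx3. With 10 splits no share under 0.05 is possible.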
